A study of Homo sapiens with 18 samples.

How the data were processed

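Messenger RNA of 18 libraries was compared in 6 groups, FOXO3 shRNA and scrambled shRNA in each of BL-41, Namalwa and Jiyoye. Libraries were made with oligo-dT enrichment, per the labels' protocols. Reads were filtered with SOAPnuke, per the series' design text, and Bowtie2, RSEM and DESeq2 with the hg38 genome are named in the submitters' processing notes, with no versions. For each line the authors deposited 1 table. It holds 1 signal value per arm, which the authors normalized by library size factors and moderated, and no value per library. The arm values are never 0 and their ratio is the moderated fold change, so they are not plain group means. The log2 fold change that the authors deposited is that of FOXO3 shRNA over scrambled shRNA, moderated towards 0. The deposited p-values and adjusted p-values come from the authors' DESeq2 test, per the series' design text. The ratio of the arm values was checked to equal the deposited fold change (largest difference 1.39e-14), and the adjusted p recomputed by the Benjamini-Hochberg method equalled the deposited one (largest difference 3.56e-15).

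A count test with values per library, which had been planned, could not be run, so each line's calls are the authors' own at an adjusted p under 0.05. The SE of each fold change was recovered from the authors' fold change and p, as the fold change over the normal quantile of p. Depth was read from low genes, whose values were whole-read sums within a tolerance of 1e-07 for 1460 genes in BL-41, 1570 in Namalwa and 1488 in Jiyoye. Size factors ran from 0.950 to 1.10 in BL-41, from 0.985 to 1.02 in Namalwa and from 0.963 to 1.08 in Jiyoye. The median SE was 0.144, 0.127 and 0.149 over the 9884, 9671 and 10122 genes with a mean of at least 100 in these lines, and 0.508, 0.254 and 0.452 over genes with a mean under 10, where moderation bounds it. Changes of low genes are therefore understated.

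Differences between lines were tested with a z test on the difference of fold changes, with Benjamini-Hochberg adjustment within each of the 3 pairs. Shared calls were set against the product of the lines' call rates. Gene lists, 33 in number with 794 members and fixed before the data were examined, were tested with two-sided Fisher's exact tests of called members against other genes, adjusted over 96 tests. Of these lists 32 had measured members, and the mitochondrially encoded genes were not analysed here. Tests by direction, adjusted together, were added after the data were seen. Each list's median was placed among 10000 random lists matched on mean expression in 20 bins. Members of a list are not independent, and without values per library their correlation could not be estimated, so the list p-values can be too small. Annotation terms of 10 to 500 genes were tested with one-sided Fisher's exact tests.

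Named genes followed a rule fixed before the data were examined. It takes the FOXO genes, the 8 largest rises and 8 largest falls per line among called genes with a mean of at least 100, the 10 largest mean rises and falls among genes called alike in the 3 lines with that mean in each, 4 members with the smallest adjusted p for each list described in a line, and 3 genes per pair of lines with that mean in both and the smallest p of a difference past its test. Described lists are those past a list test in that line, with the FOXO target genes and the myeloid markers in every line, 25 in all. That definition was set after the data were seen and gave 124 genes, of which 4 are not reported here.

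Words of 6 and 7 bases were tied to the fold change by linear regression on presence in the 5' UTR, the coding sequence or the 3' UTR of the canonical transcript (GENCODE 44), with length and GC content as covariates and residuals limited to 2 in size, for genes with a mean of at least 100 in each line and a part of at least 30 bases. Coordinates are those of GRCh38 and gene names were matched through a RefSeq table of GRCh38.p14. A canonical transcript was found for 14255 of 14549 genes (98.0%). Intervals of shares are exact binomial at 95% and cover sampling of genes only, and ratios of shares divide those intervals by the expected share. For the split choice of hexamers, genes were drawn at random into 2 sets, and the word with the lowest or highest z for the mean of the lines in the 3' UTR was taken from each. Shares of carriers, unlike the regressions, count a word anywhere in the transcript. The SE of a difference of medians came from 2000 bootstrap draws. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

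The difference test was tested on simulated data. The noise was independent between genes and drawn from the same SE that the test used. A false share near the threshold therefore follows from the adjustment, and whether the recovered SE are right was not tested. The changed genes were drawn from those with a mean of at least 100 in both lines, so recovery of lower genes was not tested. For BL-41 against Namalwa (14789 genes) the test recovered 86% of changes of 1 on the log2 scale and 18% of changes of 0.5. Of its calls there, 4.59% were false. For BL-41 against Jiyoye (15419 genes) these were 87%, 20% and 4.46%, and for Namalwa against Jiyoye (14933 genes) 89%, 17% and 4.51%. For BL-41 (16001 genes), 3% of 200 unchanged lists had a p under 0.05. Calls and list members were drawn there independently at random, so lists whose members change together were not tested. A hexamer planted with a fall of 0.3 among 9750 genes ranked 1 and was recovered at -0.32. That fall was larger in size than the changes tied to either hexamer in the 3' UTR, and its noise was independent between genes. Alternatives were a stricter adjusted p of 0.01, a log2 fold change of at least 1 or 0.58 in size, a mean of at least 100, lists of unmatched genes, genes without either hexamer, moderation undone, lines left out and another background for terms.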

Results

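The study asked what follows loss of the transcription factor FOXO3 in Burkitt lymphoma, a B cell cancer driven by MYC. Messenger RNA was profiled in 3 established Burkitt lymphoma lines, BL-41, Namalwa and Jiyoye, of which Namalwa and Jiyoye carry Epstein-Barr virus. Cells of each line received a lentivirus coding for a short hairpin RNA (shRNA) against FOXO3 or for a scrambled shRNA, and infected cells were sorted on day 4. Each of the 6 groups held 3 libraries, 18 in all. The labels call them triplicates and do not say that they came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The deposited tables gave 1 normalized value per arm, which carries the moderation of the fold change, and no value per library, so no SD between libraries is given. Errors below are standard errors (SE) recovered from the authors' fold change and p. Relative library sizes were estimated as the size factor times the line's summed mean value, and are not read totals. In BL-41 they ran from 18035639 to 19921339 with scrambled and from 17207943 to 17737406 with FOXO3 shRNA. In Namalwa these ranges were 17949484 to 18137073 and 18418024 to 18656265. In Jiyoye they were 16920503 to 18533917 and 16541329 to 16870341. The arms thus did not overlap in any line, and FOXO3 shRNA had the larger sizes only in Namalwa. All fold changes are FOXO3 shRNA over scrambled shRNA on the log2 scale.

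FOXO3 is a forkhead transcription factor that AKT holds outside the nucleus. Its gene lies on chromosome 6 from 108559835 to 108684774 (GRCh38). The FOXO3 transcript fell in BL-41 and in Namalwa and was not called in Jiyoye. In the authors' deposited table, the FOXO3 value was 944.5 with scrambled shRNA and 544.7 with FOXO3 shRNA in BL-41, a log2 fold change of -0.79 (recovered SE 0.14, adjusted p = 3.15e-07 by DESeq2). In Namalwa the authors' deposited table gave 850.5 and 398.4, a log2 fold change of -1.09 (recovered SE 0.16, adjusted p = 2.49e-09 by DESeq2). In Jiyoye the authors' deposited table gave 471.2 and 384, a log2 fold change of -0.30 (recovered SE 0.15, adjusted p = 0.187 by DESeq2), so a fall of the target was not shown there. The FOXO3 fold change in Namalwa minus that in Jiyoye was -0.80 and passed the test of the difference (adjusted p = 0.0174). BL-41 minus Namalwa (0.30, adjusted p = 0.486) and BL-41 minus Jiyoye (-0.50, adjusted p = 0.136) did not pass, all from the authors' deposited table. None of the related genes FOXO1, FOXO4 and FOXO6 was called by DESeq2 in any line. The log2 fold changes of FOXO1 in the authors' deposited table were 0.05 in BL-41, -0.10 in Namalwa and 0.22 in Jiyoye. Those of FOXO4 in the authors' deposited table were -0.25, -0.34 and -0.31, and those of FOXO6 were -0.19, -0.06 and 0.33.

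**Figure D1:**
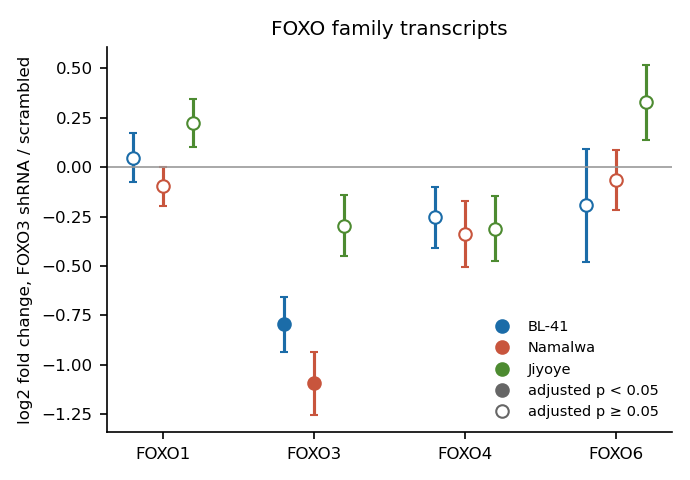
Log2 fold change (FOXO3 shRNA over scrambled shRNA, y axis) of the FOXO genes (x axis) in each line, from the authors' deposited table, with bars of 1 recovered SE on either side. Filled points have an adjusted p under 0.05, as FOXO3 has in BL-41 (-0.79) and Namalwa (-1.09).

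The first comparison asked how BL-41 responded to FOXO3 shRNA. Histone transcripts had the largest rises among called genes with a mean of at least 100. Of the genes of antigen presentation on MHC class II, 12 of 13 fell. So did 14 of 26 of the B cell programme and 10 of 21 of the plasma cell programme. Among called genes with a mean of at least 100, HIST1H1C (4.72), HIST1H2BK (3.97) and HIST1H2BD (3.92) rose most in the authors' deposited table. These are a linker histone and a pair of H2B histones, with recovered SE of 0.14, 0.15 and 0.20. AOC3, an amine oxidase, and ELK3, an ETS family factor, rose by 3.54 and 2.27, and HIST2H2BE by 2.42, in the authors' deposited table. HIST2H2AA3 and HIST2H2AA4 had the same value (3.21) in the authors' deposited table and are near-identical copies that can share reads, so each is uncertain. These 8 genes had an adjusted p from 4.66e-245 to 4.45e-11 (DESeq2). With the same limits, the largest falls in the authors' deposited table were MYL4 (-2.41), MPEG1 (-2.30), RAB4B (-2.05) and KCNN3 (-2.01). FAH (-1.94), FAM129C (-1.82), TMEM218 (-1.80) and SNRPB (-1.80) came next in the authors' deposited table. These 8 falls had an adjusted p from 1.49e-24 to 0.000116 (DESeq2). MYL4 codes for a myosin light chain, MPEG1 for a pore-forming protein, KCNN3 for a potassium channel, FAH for an enzyme of tyrosine breakdown and SNRPB for a core protein of the spliceosome.

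Among the 13 measured genes of MHC class II presentation in BL-41, 0 (with 0 at an unadjusted p under 0.05) rose, 12 fell and 1 was not called by the authors' DESeq2 test (0 rose and 12 fell adjusted over the list alone). MHC class II presentation in BL-41 gave an adjusted p of 0.000244 by Fisher's exact test for calls in either direction and of 1.06e-07 for members that fell. HLA-DRB1 (-1.13), CD74 (-1.09), HLA-DRA (-1.19) and HLA-DQA1 (-1.12) fell in the authors' deposited table, where CD74 is the invariant chain of MHC class II (adjusted p from 3.9e-14 to 2.01e-12, DESeq2). Of 26 genes of B cell identity and receptor signalling, 0 (with 0 at an unadjusted p under 0.05) rose, 14 fell and 12 were not called by the authors' DESeq2 test (0 rose and 14 fell adjusted over the list alone). B cell identity and receptor signalling in BL-41 gave an adjusted p of 0.0994 by Fisher's exact test for calls in either direction and of 8.02e-05 for members that fell. SPIB, a B cell transcription factor, BLNK, a linker of the B cell receptor, and CD79B, a chain of that receptor, fell by 1.15, 1.16 and 0.84 in the authors' deposited table (adjusted p from 3.72e-12 to 9.92e-11, DESeq2). Of 21 plasma cell differentiation genes in BL-41, 1 rose, 10 fell and 10 were not called by the authors' DESeq2 test (1 rose and 10 fell adjusted over the list alone). Plasma cell differentiation in BL-41 gave an adjusted p of 0.169 by Fisher's exact test for calls in either direction and of 0.00502 for members that fell. JCHAIN (-1.42), TNFRSF17 (-1.45), CD38 (-1.05) and PIM2 (-1.21) fell in the authors' deposited table, JCHAIN being the joining chain of polymeric antibodies (adjusted p from 5.45e-16 to 1.37e-07, DESeq2). The member that rose in BL-41 was IRF4 (0.54 in the authors' deposited table, adjusted p = 0.00157, DESeq2), which fell in the other lines. Of 15 genes of MHC class I presentation in BL-41, 0 (with 1 at an unadjusted p under 0.05) rose, 7 fell and 8 were not called by the authors' DESeq2 test (0 rose and 9 fell adjusted over the list alone). MHC class I presentation in BL-41 gave an adjusted p of 0.416 by Fisher's exact test for calls in either direction and of 0.0298 for members that fell. ERAP1 (-0.98), HLA-B (-0.72), PSMB10 (-0.48) and PSMB9 (-0.64) fell in the authors' deposited table (adjusted p from 6.35e-10 to 0.00667, DESeq2). Beside these groups, of 10 measured myeloid markers 3 rose in BL-41, and LYZ, CD14 and CD68 had log2 fold changes of 1.5, 2.34 and 0.92 in the authors' deposited table (adjusted p from 4e-06 to 0.0143, DESeq2), while AIF1 (0.47, adjusted p = 0.117) was not called.

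The integrated stress response reshapes translation when amino acids or protein folding fail. Of 32 of its genes in BL-41, 0 (with 3 at an unadjusted p under 0.05) rose, 16 fell and 16 were not called by the authors' DESeq2 test (2 rose and 18 fell adjusted over the list alone). Integrated stress response in BL-41 gave an adjusted p of 0.113 by Fisher's exact test for calls in either direction and of 8.01e-05 for members that fell. ASNS (-1.15), ATF5 (-0.95), SLC7A5 (-1.07) and TRIB3 (-0.95) fell in the authors' deposited table, ASNS being asparagine synthetase and SLC7A5 an amino acid transporter (adjusted p from 8.33e-13 to 1.02e-07, DESeq2). Of 29 replication-dependent histone genes in BL-41, 15 rose, 0 (with 2 at an unadjusted p under 0.05) fell and 14 were not called by the authors' DESeq2 test (15 rose and 1 fell adjusted over the list alone). Replication-dependent histones in BL-41 gave an adjusted p of 0.113 by Fisher's exact test for calls in either direction and of 8.02e-05 for members that rose. These libraries were made from oligo-dT selected RNA, while most replication-dependent histone messages lack a poly(A) tail. Of 18 heat shock genes in BL-41, 9 rose, 1 fell and 8 were not called by the authors' DESeq2 test (9 rose and 1 fell adjusted over the list alone). Heat shock response in BL-41 gave an adjusted p of 0.146 by Fisher's exact test for calls in either direction and of 0.00669 for members that rose. HSPH1, HSPA8 and HSPB1 rose by 1.30, 0.91 and 0.86 and HSPA6 had a fold change of -1.51 in the authors' deposited table (adjusted p from 3.29e-11 to 2.07e-07, DESeq2). Of 33 genes of the BCL2 family and apoptosis in BL-41, 12 rose, 3 fell and 18 were not called by the authors' DESeq2 test (13 rose and 3 fell adjusted over the list alone). BCL2 family and apoptosis in BL-41 gave an adjusted p of 0.206 by Fisher's exact test for calls in either direction and of 0.018 for members that rose. The caspase genes CASP10 and CASP8 rose by 1.91 and 0.92 and HRK, a death-promoting BCL2 family member, had a fold change of -0.80 in the authors' deposited table (adjusted p from 1.51e-09 to 0.000172, DESeq2). Of 51 cytosolic ribosomal protein genes in BL-41, 19 rose, 1 fell and 31 were not called by the authors' DESeq2 test (22 rose and 1 fell adjusted over the list alone). Cytosolic ribosomal proteins in BL-41 gave an adjusted p of 0.359 by Fisher's exact test for calls in either direction and of 0.0013 for members that rose. RPL6 and RPL23 rose by 0.45 and 0.41 and RPL11 had a fold change of -0.44 in the authors' deposited table (adjusted p from 0.000122 to 0.000767, DESeq2). Of 42 FOXO target genes in BL-41, 9 rose, 9 fell and 24 were not called by the authors' DESeq2 test (11 rose and 10 fell adjusted over the list alone). FOXO target genes in BL-41 gave an adjusted p of 0.215 by Fisher's exact test for calls in either direction and of 0.569 for members that rose. S1PR1, ULK1, FBXO32 and KLF2 rose by 1.70, 1.04, 1.33 and 1.06 in the authors' deposited table (adjusted p from 1.58e-18 to 1.24e-08, DESeq2).

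Over all genes, 4591 of 16001 tested in BL-41 were called at an adjusted p under 0.05 by DESeq2, 2314 up and 2277 down. With a log2 fold change of at least 1 in size as well, 899 were called, 459 up and 440 down. The median SE over genes with a mean of at least 100 was 0.144, which sets the size of change that could be called in such genes. The lists were tested for calls in either direction as fixed before the data were examined, and of these 96 tests 5 passed. The tests by direction were added after the data were seen, and of these 192 tests 19 passed, 8 for rising and 11 for falling members. They were not repeated over genes with a mean of at least 100, of which 4026 of 9884 were called in BL-41. That higher rate can lift lists of well-expressed genes. In either direction over such genes, Fisher's exact test gave an adjusted p of 0.00398 for MHC class II and 0.133 for histones in BL-41. Other lists past a test by direction gave at least 0.573 in BL-41 and 0.12 to 0.858 in Jiyoye. In Namalwa the histone (0.00077) and plasma cell (0.00246) lists passed.

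The second comparison asked the same of Namalwa, the line with the lowest FOXO3 fold change. The replication-dependent histone genes that were called all rose, and the plasma cell, interferon-stimulated and MHC class I genes that were called all fell, though most members of each of these lists were not called. Among called genes with a mean of at least 100, HIST1H2BK (4.01), HIST1H2BD (2.81) and HIST1H1C (2.70) rose most in the authors' deposited table. HIST2H2AA3 (2.42) and HIST2H2AA4 (2.42) came next there, then CTNND1, which codes for the junction protein p120 catenin (1.75). HIST2H2BE (1.52) and DYNLRB1, a dynein light chain (1.47), followed in the authors' deposited table. HIST2H2AA3 and HIST2H2AA4 are uncertain here too, and the 8 genes had an adjusted p from 1.72e-224 to 0.00238 (DESeq2). With the same limits, the largest falls in the authors' deposited table were SLC39A6 (-1.68), RAB4B (-1.59), SNRPB (-1.53) and RNASEK (-1.49). UBE2Z (-1.48), PDXP (-1.40), FGFRL1 (-1.29) and GCSAM (-1.24) came next in the authors' deposited table. These 8 falls had an adjusted p from 7.29e-50 to 3.58e-17 (DESeq2). SLC39A6 codes for a zinc transporter, RAB4B for a GTPase of endosomes, UBE2Z for a ubiquitin-conjugating enzyme and GCSAM for a germinal centre B cell protein.

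Of 28 replication-dependent histone genes in Namalwa, 10 rose, 0 (with 0 at an unadjusted p under 0.05) fell and 18 were not called by the authors' DESeq2 test (14 rose and 0 fell adjusted over the list alone). Replication-dependent histones in Namalwa gave an adjusted p of 0.000244 by Fisher's exact test for calls in either direction and of 1.06e-07 for members that rose. HIST1H2AC, an H2A histone, rose by 2.64 in the authors' deposited table (adjusted p = 5.61e-19, DESeq2). Of 21 plasma cell differentiation genes in Namalwa, 0 (with 0 at an unadjusted p under 0.05) rose, 8 fell and 13 were not called by the authors' DESeq2 test (0 rose and 9 fell adjusted over the list alone). Plasma cell differentiation in Namalwa gave an adjusted p of 0.000851 by Fisher's exact test for calls in either direction and of 3.53e-05 for members that fell. TNFRSF17 (-0.74), MZB1 (-0.61), IRF4 (-0.42) and CD38 (-0.48) fell in the authors' deposited table, IRF4 being a transcription factor needed for plasma cells (adjusted p from 0.000623 to 0.0122, DESeq2). Of 39 interferon-stimulated genes in Namalwa, 0 (with 1 at an unadjusted p under 0.05) rose, 6 fell and 33 were not called by the authors' DESeq2 test (0 rose and 6 fell adjusted over the list alone). Interferon-stimulated genes in Namalwa gave an adjusted p of 0.175 by Fisher's exact test for calls in either direction and of 0.0354 for members that fell. MX2 (-0.95), IFI44L (-0.85), STAT2 (-0.51) and TRIM22 (-0.54) fell in the authors' deposited table, MX2 being an antiviral GTPase (adjusted p from 3.47e-10 to 0.00601, DESeq2). Of 15 genes of MHC class I presentation in Namalwa, 0 (with 1 at an unadjusted p under 0.05) rose, 5 fell and 10 were not called by the authors' DESeq2 test (1 rose and 7 fell adjusted over the list alone). MHC class I presentation in Namalwa gave an adjusted p of 0.036 by Fisher's exact test for calls in either direction and of 0.00367 for members that fell. HLA-E (-0.65), ERAP1 (-0.43), HLA-B (-0.39) and TAPBP (-0.35) fell in the authors' deposited table (adjusted p from 2.62e-05 to 0.0121, DESeq2). With members and background limited to a mean of at least 100 the test in either direction gave an adjusted p of 0.12, which ended that call, with 14 of 15 members kept and a median of -0.15 in place of -0.06. Of 41 FOXO target genes in Namalwa, 1 rose, 3 fell and 37 were not called by the authors' DESeq2 test (1 rose and 4 fell adjusted over the list alone). FOXO target genes in Namalwa gave an adjusted p of 0.64 by Fisher's exact test for calls in either direction and of 0.594 for members that fell. Their median there was nevertheless low, -0.11, at percentile 0.52 of the random lists matched on mean expression. At an unadjusted p under 0.05, 3 members rose and 10 fell in Namalwa. In BL-41 and Jiyoye the medians of FOXO target genes were above 0 (0.16 and 0.06, at percentiles 96.17 and 76.67). These percentiles were not adjusted for the number of lists. ULK1, a kinase that starts autophagy, rose by 0.47, and KLF6 (-0.39), RBL2 (-0.54) and MXI1 (-0.43) fell, in the authors' deposited table (adjusted p from 0.00172 to 0.0301, DESeq2). Over all genes, 985 of 15365 tested in Namalwa were called by DESeq2, 400 up and 585 down. With a log2 fold change of at least 1 in size as well there were 63, of which 36 rose and 27 fell. Of 8 measured myeloid markers 0 (with 0 at an unadjusted p under 0.05) rose in Namalwa, where CD14 had 0.73 in the authors' deposited table (adjusted p = 0.367, DESeq2). The median SE over genes with a mean of at least 100 was 0.127.

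The third comparison was made in Jiyoye, where FOXO3 itself was not called. More genes of DNA replication and glycolysis fell than rose, and more interferon-stimulated genes, lysosomal genes and genes of the PI3K pathway rose than fell. Most members of each of these lists were not called, and of the 5 only autophagy and lysosome passed the planned test in either direction. Among called genes with a mean of at least 100, HIST1H1C (2.96) and HIST1H2BK (2.27) rose most in the authors' deposited table. HIST2H2AA3 (2.22) and HIST2H2AA4 (2.22) came next there, then EPHX1, an epoxide hydrolase (2.09), and DYNLRB1 (1.99). WSCD2 (1.83) and H2AFX, the histone variant phosphorylated at DNA breaks (1.73), followed in the authors' deposited table. The H2A copies HIST2H2AA3 and HIST2H2AA4 are uncertain as before, and the 8 genes had an adjusted p from 4.11e-76 to 4.24e-14 (DESeq2). With the same limits, the largest falls in the authors' deposited table were MARC1 (-2.31), C2orf88 (-2.25), FHL2 (-2.10) and SNRPB (-1.89). MACROD2 (-1.88), DUSP11 (-1.77), PTPRM (-1.74) and SLC4A5 (-1.63) came next in the authors' deposited table. These 8 falls had an adjusted p from 4.05e-26 to 2.96e-10 (DESeq2). DUSP11 codes for an RNA phosphatase, PTPRM for a receptor tyrosine phosphatase and SLC4A5 for a bicarbonate transporter.

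Of 40 genes of S phase and DNA replication in Jiyoye, 1 rose, 12 fell and 27 were not called by the authors' DESeq2 test (2 rose and 15 fell adjusted over the list alone). S phase and DNA replication in Jiyoye gave an adjusted p of 0.146 by Fisher's exact test for calls in either direction and of 0.00241 for members that fell. RRM2 (-1.59), MCM7 (-0.78), RRM1 (-0.43) and POLA1 (-0.65) fell in the authors' deposited table, RRM1 and RRM2 being the subunits of ribonucleotide reductase (adjusted p from 9.6e-15 to 0.00298, DESeq2). Of 24 glycolysis genes in Jiyoye, 0 (with 0 at an unadjusted p under 0.05) rose, 8 fell and 16 were not called by the authors' DESeq2 test (0 rose and 9 fell adjusted over the list alone). Glycolysis in Jiyoye gave an adjusted p of 0.209 by Fisher's exact test for calls in either direction and of 0.00986 for members that fell. TPI1 (-0.82), GAPDH (-0.47), PKM (-0.42) and ENO1 (-0.57) fell in the authors' deposited table (adjusted p from 5.38e-07 to 0.0132, DESeq2). Of 21 plasma cell differentiation genes in Jiyoye, 1 rose, 7 fell and 13 were not called by the authors' DESeq2 test (1 rose and 8 fell adjusted over the list alone). Plasma cell differentiation in Jiyoye gave an adjusted p of 0.146 by Fisher's exact test for calls in either direction and of 0.018 for members that fell. IRF4 (-1.5), SLAMF7 (-1.59), TXNDC5 (-0.66) and PIM2 (-0.66) fell in the authors' deposited table (adjusted p from 1.64e-14 to 2.62e-05, DESeq2). Of 38 interferon-stimulated genes in Jiyoye, 9 rose, 3 fell and 26 were not called by the authors' DESeq2 test (12 rose and 6 fell adjusted over the list alone). Interferon-stimulated genes in Jiyoye gave an adjusted p of 0.169 by Fisher's exact test for calls in either direction and of 0.0447 for members that rose. IRF9, LY6E and EIF2AK2 rose by 1.04, 1.03 and 1.09 in the authors' deposited table, EIF2AK2 being a kinase that senses double-stranded RNA (adjusted p from 3.07e-12 to 1.39e-10, DESeq2). Of 29 genes of autophagy and the lysosome in Jiyoye, 9 rose, 5 fell and 15 were not called by the authors' DESeq2 test (11 rose and 6 fell adjusted over the list alone). Autophagy and lysosome in Jiyoye gave an adjusted p of 0.00303 by Fisher's exact test for calls in either direction and of 0.00886 for members that rose. ULK1, CTSZ, CTSD and TFEB rose by 1.03, 0.86, 0.65 and 0.65 in the authors' deposited table, TFEB being a transcription factor of lysosomal genes (adjusted p from 2.55e-12 to 3.58e-06, DESeq2). With the background limited to genes with a mean of at least 100 the test in either direction gave an adjusted p of 0.12, which ended that call. All 29 members were kept and their median was 0.21 in both, so only the genes they were set against changed.

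The PI3K pathway activates AKT, which keeps FOXO factors out of the nucleus. Of 30 of its genes in Jiyoye, 9 rose, 1 fell and 20 were not called by the authors' DESeq2 test (9 rose and 2 fell adjusted over the list alone). PI3K, AKT and mTOR pathway in Jiyoye gave an adjusted p of 0.169 by Fisher's exact test for calls in either direction and of 0.01 for members that rose. PIK3CD and AKT1 rose by 0.61 and 0.50 and PDPK1 had a fold change of -0.54 in the authors' deposited table (adjusted p from 8.47e-06 to 0.000314, DESeq2). Of 41 FOXO target genes in Jiyoye, 5 rose, 3 fell and 33 were not called by the authors' DESeq2 test (8 rose and 3 fell adjusted over the list alone). FOXO target genes in Jiyoye gave an adjusted p of 0.884 by Fisher's exact test for calls in either direction and of 0.845 for members that rose. ULK1, GABARAPL1 and CDKN2D rose by 1.03, 0.75 and 1.07 and TXNIP, a thioredoxin-binding protein, had a fold change of -0.77 in the authors' deposited table (adjusted p from 2.55e-12 to 0.000254, DESeq2). Over all genes, 2919 of 16787 tested in Jiyoye were called by DESeq2, 1458 up and 1461 down. With a log2 fold change of at least 1 in size as well there were 457, of which 220 rose and 237 fell. Of 11 measured myeloid markers 1 rose in Jiyoye, CD14 with 1.33 in the authors' deposited table (adjusted p = 0.0447, DESeq2), and 0 did so adjusted over the list alone. The median SE over genes with a mean of at least 100 was 0.149. Since FOXO3 was not called in this line, no direction here is tied to its loss.

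**Figure D2:**
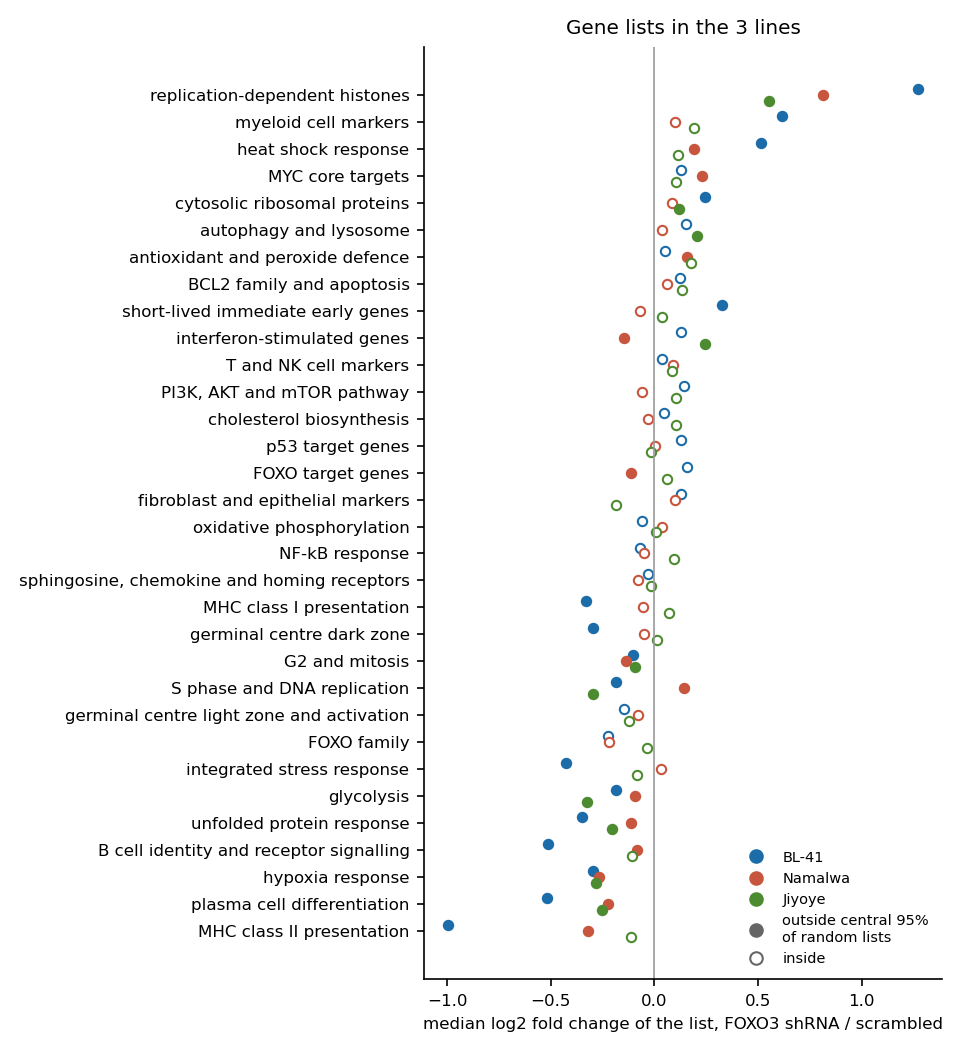
Median log2 fold change (FOXO3 shRNA over scrambled shRNA, x axis) of each of 32 gene lists (y axis) in the 3 lines, computed from the authors' deposited table. Filled points lie outside the central 95% of 10000 random lists matched on mean expression, as 40 of 96 did, and the replication-dependent histones had the highest median in BL-41 (1.27). Only 5 of those 29 histone genes had a mean of at least 100 there, with a median of 3.92.

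The next comparison asked which genes responded alike in the 3 lines. HIST1H1C and some other histone genes rose in each line, and SNRPB, RAB4B and RNASEK were among those that fell in each. SNRPB, RAB4B and RNASEK carry the word CCCGTA in the 3' UTR, which is taken up below. As a list, replication-dependent histones passed neither test in Jiyoye, where 7 of 29 rose (adjusted p = 0.64 by Fisher's exact test in either direction and 0.0782 for members that rose). Among genes called alike in the 3 lines with a mean of at least 100 in each, the mean rises were largest for HIST1H1C, HIST1H2BK, HIST1H2BD, HIST2H2AA3 and HIST2H2AA4, followed by DYNLRB1, NME1-NME2, LGALS3BP, H2AFX and ATP6V0C. In the authors' deposited table, LGALS3BP, a secreted glycoprotein, rose by 2.02 in BL-41, 1.26 in Namalwa and 1.21 in Jiyoye. ATP6V0C, a subunit of the proton pump of lysosomes, rose by 1.78, 0.77 and 1.41 in the same order in the authors' deposited table. NME1-NME2, a readthrough gene whose reads its parent genes share and which is therefore uncertain, had 1.89, 1.26 and 1.63 in the authors' deposited table. SNRPB had -1.80, -1.53 and -1.89 in BL-41, Namalwa and Jiyoye in the authors' deposited table. RAB4B had -2.05, -1.59 and -1.26, and RNASEK -1.71, -1.49 and -1.5, in the authors' deposited table. Of the other genes with the largest mean falls, the log2 fold changes in the authors' deposited table were in the same order -1.30, -1.48 and -1.58 for UBE2Z and -1.42, -1.40 and -1.41 for PDXP. SLC39A6, TMEM218, ABRAXAS1, GCSAM and FUNDC2 completed the 10, with values in Jiyoye of -1.32, -1.63, -1.62, -1.14 and -1.32 in the authors' deposited table.

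**Figure D3:**
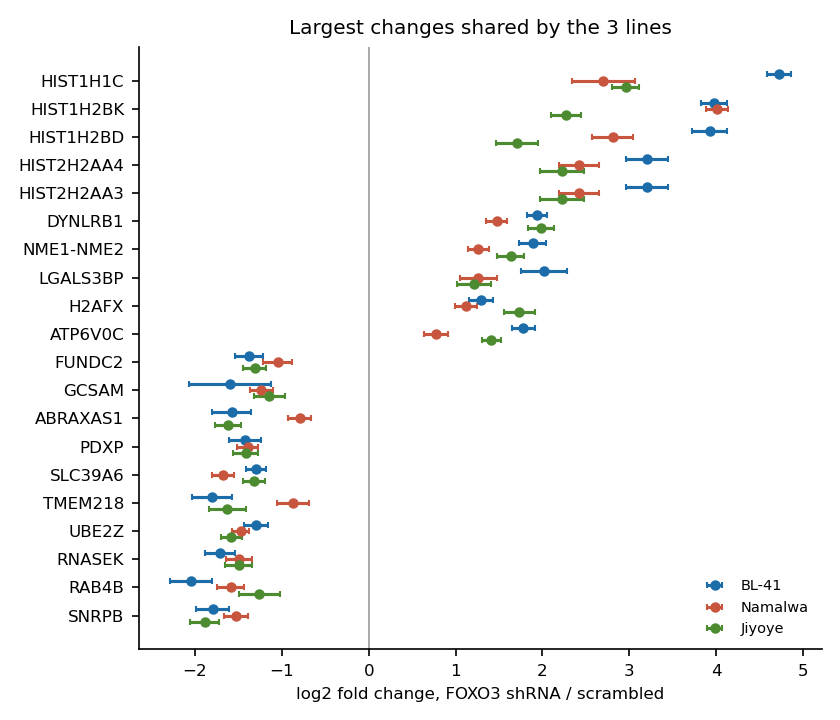
Log2 fold change (FOXO3 shRNA over scrambled shRNA, x axis) of the 10 genes with the largest mean rise and the 10 with the largest mean fall among genes called the same way in the 3 lines with a mean of at least 100 in each (y axis), from the authors' deposited table, with bars of 1 recovered SE on either side. HIST1H1C (4.72 in BL-41) lies farthest to the right and SNRPB has -1.89 in Jiyoye.

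Of 14549 genes tested in each of the 3 lines, 215 rose in all of them, where 6.18 would have done so had the lines been independent, and 263 fell, against 8.68. Among 8870 genes with a mean of at least 100 in each line 202 rose, against 9.67, and 237 fell, against 11.5, so the excess for rises was 20.9 times and no longer 34.8 times. The lines share no libraries. Between BL-41 and Namalwa 307 genes rose in both and 428 fell in both. Between BL-41 and Jiyoye the counts were 739 and 747, and between Namalwa and Jiyoye 248 and 318. Opposite calls were fewer than independence gives: 3 genes rose in BL-41 and fell in Namalwa (91.6 under independence) and 2 did the reverse (61.9), 24 rose in BL-41 and fell in Jiyoye (222) and 49 did the reverse (220.5), and 1 rose in Namalwa and fell in Jiyoye (38.7) while 8 did the reverse (56.95). Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.536 (Spearman's rho 0.499) for BL-41 and Namalwa, 0.444 (rho 0.436) for BL-41 and Jiyoye and 0.447 (rho 0.427) for Namalwa and Jiyoye. Of the 3 pairs of lines, the same sign was found for 67.8%, 66.2% and 65.3% of genes in that order. A mean log2 fold change of at least 1 over the lines was found for 115 genes and of at most -1 for 68.

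The response itself was then compared between lines, by a z test of the difference of the deposited fold changes with their recovered SE. JCHAIN, IRF4, CTNND1 and histone genes were among those that differed. JCHAIN fell in BL-41 and was not called in Namalwa, where it had -0.05 (adjusted p = 0.865, DESeq2; difference -1.37, from the authors' deposited table), and BCL9L (1.69) and HELZ2 (1.91) also had the smallest p of that pair. CTNND1 differed by 2.22 between BL-41 and Jiyoye and by 2.18 between Namalwa and Jiyoye, as the first line minus the second, from the authors' deposited table. For BL-41 minus Jiyoye the difference was 1.76 for HIST1H1C and 2.04 for IRF4, and for Namalwa minus Jiyoye it was 1.74 for HIST1H2BK and 1.81 for DUSP11, all from the authors' deposited table. In total 1037 of 14789 genes differed between BL-41 and Namalwa, 963 of 15419 between BL-41 and Jiyoye and 410 of 14933 between Namalwa and Jiyoye, at an adjusted p under 0.05. Most genes called in 1 line alone did not pass this test: of 3813 genes called in BL-41 and not in Namalwa, 884 differed, and of 2272 called in Jiyoye and not in Namalwa, 338 did.

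Annotation terms given in the deposited tables were tested for enrichment with Fisher's exact test (one-sided), over all genes tested and, as an alternative added after the data were seen, over annotated genes with a mean of at least 100. The background changed the calls, so only terms past the threshold in both are named. In BL-41, 10 of 12 genes of the MHC class II protein complex fell (adjusted p = 0.000298, and 0.000617 in the second background). Also falling there were 10 of 21 genes of the transport vesicle membrane (0.0381 and 0.00894), of which 5 belong to that complex, and 9 of 18 of glutathione derivative synthesis (0.041 and 0.044). Of 33 genes annotated to transferrin transport, 16 rose in BL-41 (adjusted p = 0.00187 and 0.00194). The 11 of 24 genes of phagosome acidification that rose (0.0359 and 0.0345) and the 10 of 18 with rotary proton pump activity (0.015 and 0.0479) were all among these 16, so the 3 terms rest largely on the subunits of 1 proton pump. Further terms for rising genes in BL-41 were negative regulation of transcription (85 of 341 genes, 0.0467 in the second background) and of RNA polymerase II promoters (113 of 494, 0.0393), serine/threonine kinase activity (81 of 321, 0.0393) and corepressor activity (48 of 173, 0.0419). In Namalwa, 28 of 199 genes of mRNA splicing via the spliceosome rose (adjusted p = 1.71e-09 and 1.45e-05), as did 8 of 19 genes of the tri-snRNP complex (3.29e-05 and 0.00498), all 8 of them among the 28. The related terms RNA splicing (18 of 162 genes, 0.047 in the second background) and mRNA processing (18 of 177, 0.0385) shared 13 and 9 genes with the 28. In Jiyoye, 11 of 21 genes of the ciliary transition zone fell (adjusted p = 0.00198 and 0.0211). In total 42 terms passed for rising and 14 for falling genes in BL-41 (7 and 3 in the second background), and 3 and 6 in Jiyoye (0 and 1 there). In Namalwa 9 terms passed for rising genes (4 in the second background) and 0 for falling genes by Fisher's exact test, where 91 had an unadjusted p under 0.05 (0 and 62 in the second background). For Jiyoye's rising genes 151 terms had an unadjusted p under 0.05 in the second background.

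Transcripts were also searched for short words. The hexamer CCCGTA was the word tied to the lowest fold changes in the 3' UTR in each line, by 24 scans over parts of the transcript, word lengths and lines that were run after a first look at these data with a lower expression minimum. Over 8765 genes the log2 fold change of carriers differed from that of other genes by -0.21 (SE 0.0223) in BL-41, -0.17 (SE 0.0120) in Namalwa and -0.13 (SE 0.0177) in Jiyoye. In the coding sequence, over 8793 genes, it differed by -0.139 (SE 0.0197), -0.0842 (SE 0.0107) and -0.101 (SE 0.0157) in the same order. These SE are over genes, taken as independent, and do not cover a spread between libraries that genes share. Of 261 genes that fell in all 3 lines and have a canonical transcript, 99 carried the hexamer (37.9%, exact 95% confidence interval 32.0% to 44.1%), against 11.7% among uncalled genes of like length and GC content. FOXO3 carries it in the coding sequence at position 1534 of the transcript (chromosome 6 from 108664075 to 108664080, GRCh38), and SNRPB carries it in the 3' UTR (chromosome 20 from 2461715 to 2461720). FOXO1, which was not called in any line, also carries CCCGTA, in the 5' UTR at position 4. Of 215 genes that rose in all 3 lines, 119 carried TCGCCC (55.3%, exact interval 48.4% to 62.1%), against 39.7% in uncalled genes of like length and GC content. For rises TCGCCC ranked 30 in BL-41, 2 in Namalwa and 1 in Jiyoye of 4096 hexamers in the 3' UTR, and 3, 5 and 1 in the coding sequence. FOXO3 also carries TCGCCC in the coding sequence, at positions 1265, 1322 and 1496. Both hexamers were found in these data, so these shares describe the genes that led to them. The choice was therefore repeated, after these shares were seen, in each of 2 random sets of genes of like size, and carriers were counted in the set not used for the choice. Each set gave CCCGTA for falls, and 38% and 37.9% of the genes that fell in all 3 lines carried it in the set not used, against 12.6% and 11%. For rises the sets gave TTTTAA and CGGCCC, and neither gave TCGCCC. Among words of 7 bases in the 3' UTR, TCCCGTA was lowest in each line, and GTCGCCC was highest in Namalwa (z 7.42) and Jiyoye (6.59) and TTTGTTT in BL-41 (7.31). Carriers of GTCGCCC with no A after it differed from genes without TCGCCC, given length and GC content, by 0.183, 0.137 and 0.195 in BL-41, Namalwa and Jiyoye (112 genes), carriers with an A by 0.0758, 0.0701 and 0.09 (304 genes), carriers of TCGCCCA without the G by 0.0572, 0.048 and 0.0777 (174 genes), and carriers of TCGCCC alone by 0.002, -0.0246 and 0.0186 (364 genes). In the same order of lines and matches, carriers of TCCCGTA differed from genes without CCCGTA by -0.239, -0.239 and -0.204 (98 genes), with an A after it by -0.325, -0.311 and -0.281 (32 genes), of CCCGTAA without the T by -0.167, -0.15 and -0.0941 (103 genes), and of CCCGTA alone by -0.182, -0.116 and -0.0825 (234 genes).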

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

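The tests of precision, of the hexamer's strength and of other cell types were chosen only after the result was seen. The tests of differences between lines were planned. These results differed between lines by a test of the difference itself. The response differed for 1037 genes between BL-41 and Namalwa, 963 between BL-41 and Jiyoye and 410 between Namalwa and Jiyoye, at an adjusted p under 0.05. The change tied to CCCGTA in the 3' UTR also differed, by -0.0797 for BL-41 minus Jiyoye (adjusted p = 0.0155 by a z test). That test took the lines' effects as independent, though they come from the same genes. Its SE also treat genes as independent, so a spread between libraries that genes share is not covered.

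More genes were called in BL-41 (4591) and Jiyoye (2919) than in Namalwa (985), which had the lowest FOXO3 fold change, by a difference that passed its test against Jiyoye but not against BL-41 (adjusted p = 0.0174 and 0.486). A difference in precision is argued against, since the median SE was smallest in Namalwa (0.127). A stronger effect through a seed of the shRNA may add to it, but this cannot be told apart. The change tied to CCCGTA in the 3' UTR was -0.171 in Namalwa. BL-41 minus Namalwa was -0.0395 there (adjusted p = 0.119 by a z test) and -0.0545 in the coding sequence (adjusted p = 0.0451). Jiyoye had a smaller effect than Namalwa in the 3' UTR and a larger one in the coding sequence (adjusted p = 0.0907 and 0.364 by the same test). These z tests took the lines' effects as independent, though they come from the same genes, whose fold changes correlate between lines. Their SE can therefore be too large, so a difference not past its test is not shown to be absent. These SE also treat genes as independent, so a spread between libraries that genes share is not covered. They can thus be too small as well, and a difference past its test stays uncertain. Cells of another type cannot be told apart either, since at most 30% of a marker list was called up in BL-41 or Jiyoye (exact 95% interval 6.67% to 65.2%), with moderated values of CD14 at 26.69 and LYZ at 107 in the authors' deposited table under FOXO3 shRNA in BL-41, and infected cells had been sorted. Differences of biology between the lines stay open and were not tested.

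Of the named genes, these had a higher log2 fold change in BL-41 than in Namalwa, as BL-41 minus Namalwa from the authors' deposited table: AOC3 (2.54), ATP6V0C (1.01), BCL9L (1.69), CASP10 (1.68), EIF2AK2 (0.67), ELK3 (1.64), FBXO32 (1.17), HELZ2 (1.91) and HIST1H1C (2.02). Also higher in BL-41 than in Namalwa, from the authors' deposited table, were HIST1H2BD (1.12), HLA-E (0.59), HSPH1 (0.90), IRF4 (0.95), KLF2 (1.04), LYZ (1.34), NME1-NME2 (0.63), S1PR1 (1.97) and STAT2 (0.62). A higher response in BL-41 than in Namalwa, from the authors' deposited table, was found as well for ULK1 (0.57). Of the named genes, these had a lower log2 fold change in BL-41 than in Namalwa, as BL-41 minus Namalwa from the authors' deposited table: ABRAXAS1 (-0.78), ASNS (-0.74), ATF5 (-0.69), BLNK (-0.85), CD74 (-0.72), CD79B (-0.71), ENO1 (-0.51), ERAP1 (-0.55) and FAH (-1.23). Also lower in BL-41 than in Namalwa, from the authors' deposited table, were HLA-DQA1 (-0.74), HLA-DRA (-0.82), HLA-DRB1 (-0.93), HSPA6 (-1.25), JCHAIN (-1.37), KCNN3 (-1.42), MPEG1 (-1.40), PSMB9 (-0.77) and SLC4A5 (-1.05). A lower response in BL-41 than in Namalwa, from the authors' deposited table, was found as well for SLC7A5 (-1.06), TMEM218 (-0.92), TRIB3 (-0.77) and TRIM22 (-0.72).

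Of the named genes, these had a higher log2 fold change in Namalwa than in Jiyoye, as Namalwa minus Jiyoye from the authors' deposited table: ABRAXAS1 (0.82), BLNK (0.65), C2orf88 (2.08), CTNND1 (2.18), DUSP11 (1.81), FHL2 (1.89), HIST1H2AC (2.09), HIST1H2BD (1.10) and HIST1H2BK (1.74). Also higher in Namalwa than in Jiyoye, from the authors' deposited table, were IRF4 (1.09), MACROD2 (1.81), PTPRM (1.34), RRM2 (1.05), SLAMF7 (1.46), SLC4A5 (1.52) and TXNIP (0.66). Of the named genes, these had a lower log2 fold change in Namalwa than in Jiyoye, as Namalwa minus Jiyoye from the authors' deposited table: ATP6V0C (-0.64), BCL9L (-0.65), CD38 (-0.74), CD79B (-0.66), CDKN2D (-1.13), CTSZ (-0.72), EIF2AK2 (-0.93), FAM129C (-1.07) and FOXO3 (-0.80). Also lower in Namalwa than in Jiyoye, from the authors' deposited table, were GABARAPL1 (-0.80), HELZ2 (-0.60), IFI44L (-2.24), IRF9 (-0.95), LY6E (-0.72), PIK3CD (-0.64), TAPBP (-0.97), ULK1 (-0.56) and WSCD2 (-1.89).

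Of the named genes, these had a higher log2 fold change in BL-41 than in Jiyoye, as BL-41 minus Jiyoye from the authors' deposited table: AOC3 (2.32), BCL9L (1.04), C2orf88 (2.14), CASP10 (1.48), CD68 (1.45), CTNND1 (2.22), DUSP11 (1.55), ELK3 (1.62) and FBXO32 (0.91). Also higher in BL-41 than in Jiyoye, from the authors' deposited table, were FHL2 (2.64), HELZ2 (1.31), HIST1H1C (1.76), HIST1H2AC (2.02), HIST1H2BD (2.22), HIST1H2BK (1.70), HIST2H2BE (1.53), HSPA8 (0.88) and HSPH1 (1.19). A higher response in BL-41 than in Jiyoye, from the authors' deposited table, was found as well for IRF4 (2.04), MACROD2 (2.51), MARC1 (2.14), S1PR1 (1.21), STAT2 (0.59) and TXNIP (0.98). Of the named genes, these had a lower log2 fold change in BL-41 than in Jiyoye, as BL-41 minus Jiyoye from the authors' deposited table: CD38 (-1.32), CD74 (-1.16), CD79B (-1.37), CTSD (-0.60), FAM129C (-2.14), HLA-B (-0.69), HLA-DQA1 (-0.95), HLA-DRA (-1.19) and HLA-DRB1 (-1.38). Also lower in BL-41 than in Jiyoye, from the authors' deposited table, were HRK (-1.12), JCHAIN (-1.23), KCNN3 (-1.47), MPEG1 (-2.49), TAPBP (-0.74), TFEB (-0.58), TNFRSF17 (-1.20) and TRIB3 (-1.01).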

How the results depend on the processing

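Added after the data were seen were the authors' own limit of 0.58, the genes without either hexamer, the list tests by direction, the undone moderation and the second term background. In BL-41, 899 genes were called with a log2 fold change of at least 1 in size, 2546 with at least 0.58 and 2585 among genes without either hexamer. In Namalwa 526 were called at an adjusted p under 0.01, and in the order above 63, 333 and 479. In Jiyoye these were 1853, 457, 1571 and 1620. Genes that rose in all 3 lines numbered 106 at 0.01, 16 with a change of at least 1 and 93 without either hexamer, and those that fell 132, 13 and 115. Fewer genes pass these settings by construction. Among the 8545 genes without either hexamer, independence of the lines would have given 2.51 rises and 4.17 falls. The excess there was 37.0 times for rises and 27.6 times for falls, against 34.8 and 30.3 times over all genes. Over genes with a mean of at least 100, r was 0.661 for BL-41 and Namalwa, 0.619 for BL-41 and Jiyoye and 0.599 for Namalwa and Jiyoye. Without FOXO3 and the 1% of genes with the largest change, r was 0.495, 0.429 and 0.415. Over genes without either hexamer it was 0.541, 0.433 and 0.438. Genes that differed at 0.01 numbered 459, 423 and 166 for these pairs. Genes with a mean change of at least 1 numbered 61 without BL-41 and 258 without Namalwa, and those of at most -1 numbered 165 without Namalwa and 104 without Jiyoye. By direction 19 list tests passed, against 5 in either direction. With members and background of a mean of at least 100, 91 list results kept their side of the threshold, 2 gained it and 2 lost it. The 2 that gained it held a smaller share of calls than their background. Oxidative phosphorylation in BL-41 had 5 of 36 members called, all down, against 4026 of 9884 genes (adjusted p = 0.0178 by Fisher's exact test). Cytosolic ribosomal proteins in Jiyoye had 1 rise and 1 fall in 51 members, against 2579 calls in 10122 genes (adjusted p = 0.00246 by the same test). With a change of at least 1, 1 term passed for rising and 1 for falling genes in BL-41, 4 for rising genes in Namalwa, and 0 in Jiyoye by Fisher's exact test (92 rising and 53 falling at an unadjusted p under 0.05). In the second background 7 and 3 passed in BL-41, 4 rising in Namalwa, and 0 rising and 1 falling in Jiyoye (151 and 75 unadjusted). Where no construction is named, the cause was not tested.

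No paired analysis was possible because the deposited tables hold 1 value per arm and carry no replicate numbers. For the same reason the replicate block, edgeR, DESeq2 and limma refits, TMM and RLE scaling, filters on counts, a fit of all 18 libraries, leaving out each library, another pseudocount, camera and fry and an interaction model were not run, and other splits of the samples could not be counted. Depth limits low genes, whose median SE under a mean of 10 was 0.508, 0.254 and 0.452 in BL-41, Namalwa and Jiyoye.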

Other observations

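The hexamer tests and the list counts by direction were chosen only after the result was seen, and the length, GC content, FOXO3 and histone tests were written before. Hypoxia genes had low medians in each line (-0.30, -0.27 and -0.28 in BL-41, Namalwa and Jiyoye, outside the central 95% of random lists), and MYC core targets had a high median in Namalwa (0.23). For MYC core targets, 11 rose and 3 fell of 40 in BL-41, 4 and 1 of 40 in Namalwa and 3 and 1 of 40 in Jiyoye (DESeq2, and 12 up with 3 down, 9 up with 1 down and 3 up with 1 down adjusted over the list alone). For germinal centre dark zone, 2 rose and 8 fell of 25 in BL-41, 0 and 2 of 25 in Namalwa and 1 and 1 of 24 in Jiyoye (DESeq2, and 2 up with 8 down, 0 up with 2 down and 1 up with 1 down adjusted over the list alone). For germinal centre light zone and activation, 4 rose and 5 fell of 28 in BL-41, 0 and 1 of 28 in Namalwa and 1 and 5 of 28 in Jiyoye (DESeq2, and 4 up with 5 down, 0 up with 1 down and 1 up with 5 down adjusted over the list alone). For B cell identity and receptor signalling, 0 rose and 4 fell of 26 in Namalwa and 4 and 5 of 26 in Jiyoye (DESeq2, and 1 up with 6 down and 4 up with 8 down adjusted over the list alone). For S phase and DNA replication, 9 rose and 11 fell of 40 in BL-41 and 4 and 1 of 40 in Namalwa (DESeq2, and 10 up with 12 down and 6 up with 1 down adjusted over the list alone). For G2 and mitosis, 5 rose and 12 fell of 40 in BL-41, 0 and 1 of 40 in Namalwa and 3 and 6 of 40 in Jiyoye (DESeq2, and 5 up with 13 down, 0 up with 0 down and 3 up with 7 down adjusted over the list alone). For p53 target genes, 7 rose and 4 fell of 31 in BL-41, 0 and 1 of 30 in Namalwa and 0 and 3 of 31 in Jiyoye (DESeq2, and 7 up with 4 down, 1 up with 2 down and 0 up with 3 down adjusted over the list alone). For BCL2 family and apoptosis, 0 rose and 0 fell of 33 in Namalwa and 6 and 3 of 33 in Jiyoye (DESeq2, and 0 up with 0 down and 6 up with 3 down adjusted over the list alone). For antioxidant and peroxide defence, 6 rose and 5 fell of 28 in BL-41, 1 and 0 of 28 in Namalwa and 6 and 3 of 28 in Jiyoye (DESeq2, and 7 up with 5 down, 1 up with 0 down and 9 up with 3 down adjusted over the list alone). For integrated stress response, 0 rose and 1 fell of 32 in Namalwa and 2 and 7 of 32 in Jiyoye (DESeq2, and 0 up with 1 down and 2 up with 7 down adjusted over the list alone). For unfolded protein response, 1 rose and 9 fell of 25 in BL-41, 0 and 2 of 25 in Namalwa and 2 and 5 of 25 in Jiyoye (DESeq2, and 1 up with 10 down, 0 up with 2 down and 2 up with 6 down adjusted over the list alone). For heat shock response, 0 rose and 0 fell of 17 in Namalwa and 2 and 0 of 18 in Jiyoye (DESeq2, and 3 up with 0 down and 2 up with 0 down adjusted over the list alone). For interferon-stimulated genes, 5 rose and 5 fell of 39 in BL-41 (DESeq2, and 5 up with 5 down adjusted over the list alone). For NF-kB response, 6 rose and 6 fell of 28 in BL-41, 0 and 0 of 28 in Namalwa and 1 and 5 of 28 in Jiyoye (DESeq2, and 6 up with 7 down, 0 up with 0 down and 1 up with 5 down adjusted over the list alone).

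For glycolysis, 1 rose and 6 fell of 24 in BL-41 and 0 and 0 of 24 in Namalwa (DESeq2, and 1 up with 6 down and 0 up with 0 down adjusted over the list alone). For hypoxia response, 1 rose and 6 fell of 20 in BL-41, 0 and 1 of 20 in Namalwa and 0 and 1 of 20 in Jiyoye (DESeq2, and 1 up with 6 down, 0 up with 1 down and 0 up with 1 down adjusted over the list alone). For cholesterol biosynthesis, 3 rose and 6 fell of 25 in BL-41, 0 and 2 of 25 in Namalwa and 2 and 1 of 25 in Jiyoye (DESeq2, and 3 up with 8 down, 0 up with 2 down and 2 up with 1 down adjusted over the list alone). For oxidative phosphorylation, 0 rose and 5 fell of 36 in BL-41, 0 and 2 of 36 in Namalwa and 1 and 4 of 36 in Jiyoye (DESeq2, and 0 up with 5 down, 0 up with 3 down and 1 up with 4 down adjusted over the list alone). For cytosolic ribosomal proteins, 0 rose and 1 fell of 51 in Namalwa and 1 and 1 of 51 in Jiyoye (DESeq2, and 0 up with 1 down and 0 up with 0 down adjusted over the list alone). For replication-dependent histones, 7 rose and 0 fell of 29 in Jiyoye (DESeq2, and 8 up with 0 down adjusted over the list alone). For MHC class I presentation, 3 rose and 1 fell of 15 in Jiyoye (DESeq2, and 3 up with 2 down adjusted over the list alone). For MHC class II presentation, 0 rose and 3 fell of 13 in Namalwa and 0 and 2 of 13 in Jiyoye (DESeq2, and 0 up with 6 down and 0 up with 2 down adjusted over the list alone). For autophagy and lysosome, 10 rose and 4 fell of 29 in BL-41 and 1 and 0 of 29 in Namalwa (DESeq2, and 10 up with 4 down and 1 up with 0 down adjusted over the list alone). For PI3K, AKT and mTOR pathway, 7 rose and 7 fell of 30 in BL-41 and 0 and 1 of 30 in Namalwa (DESeq2, and 9 up with 7 down and 0 up with 1 down adjusted over the list alone). For sphingosine, chemokine and homing receptors, 6 rose and 5 fell of 22 in BL-41, 0 and 1 of 22 in Namalwa and 2 and 0 of 22 in Jiyoye (DESeq2, and 6 up with 6 down, 0 up with 1 down and 2 up with 0 down adjusted over the list alone). For T and NK cell markers, 1 rose and 1 fell of 12 in BL-41, 0 and 0 of 12 in Namalwa and 1 and 0 of 14 in Jiyoye (DESeq2, and 1 up with 1 down, 0 up with 0 down and 1 up with 0 down adjusted over the list alone). For fibroblast and epithelial markers, 2 rose and 0 fell of 9 in BL-41, 0 and 0 of 8 in Namalwa and 0 and 3 of 10 in Jiyoye (DESeq2, and 2 up with 0 down, 0 up with 0 down and 0 up with 3 down adjusted over the list alone). For short-lived immediate early genes, 7 rose and 2 fell of 21 in BL-41, 0 and 2 of 21 in Namalwa and 2 and 0 of 21 in Jiyoye (DESeq2, and 7 up with 2 down, 0 up with 2 down and 2 up with 0 down adjusted over the list alone). Where a count was 0 by DESeq2, between 0 and 8 members had an unadjusted p under 0.05 in that direction.

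Genes that fell in all 3 lines were the first pattern weighed. Transcript length and GC content are argued against, since they alone gave at most 5.09% of the genes' median change in any line. The genes were chosen as called down, which enlarges their observed median and lowers that share. The median changes that length and GC content gave were -0.0037, -0.0274 and -0.0366 in BL-41, Namalwa and Jiyoye. Loss of FOXO3 cannot be told apart: the median in Jiyoye minus that in Namalwa was -0.129 (bootstrap SE 0.0258 over genes), but the genes were chosen because they were called in both lines, so this decides nothing. The hypothesis that the FOXO3 shRNA represses transcripts matching its seed may account for part of the falls, since CCCGTA was chosen in each of 2 random sets of genes and, in the set not used for the choice, was carried 3.23 times as often as by uncalled genes of like length and GC content (2.72 to 3.75 from the exact interval of the share). The shRNA's sequence was not used here, and 162 of the genes lacked the hexamer. Their medians were -0.87, -0.59 and -0.72 in BL-41, Namalwa and Jiyoye, and those of carriers -0.87, -0.58 and -0.71. All were chosen because they were called down in each line, so these medians decide nothing about the seed.

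Genes that rose in all 3 lines were the second pattern. Length and GC content alone gave at most 6.4% of their median change. Their choice as called genes lowers that share too. The median changes that length and GC content gave were 0.0384, -0.0291 and 0.0433 in BL-41, Namalwa and Jiyoye. The scrambled shRNA, as the control, may repress transcripts of its own, but this cannot be told apart. TCGCCC was chosen in neither set. The words chosen were carried 1.09 times as often in the set not used as by uncalled genes of like length and GC content (0.969 to 1.2). That count took the whole transcript, where shares of 54.9% and 60.4% were expected for TTTTAA and CGGCCC. It could therefore hardly show an effect confined to the 3' UTR. The shRNA's sequence was not used here. The extension GTCGCCC had the highest z of the words of 7 bases in Namalwa and Jiyoye (not BL-41) in the data it was found in. For the histone genes, a rise of histone transcripts of all kinds is argued against: 11 replication-independent genes reached -0.293% of the replication-dependent median where that share was highest, with 0 called up by DESeq2 in any line and 0 rising at an unadjusted p under 0.05, and 3 called down in BL-41 and 1 in Jiyoye, though H2AFX, which was placed in neither group, rose in each line (1.29, 1.12 and 1.73 in the authors' deposited table). Whether replication-dependent histone messages gained poly(A) tails in these cells stays open, as it was not tested.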
